A study of Mus musculus with 6 samples.

How the data were processed

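Bulk RNA was sequenced from the microdissected cochlear lateral wall of 3 young and 3 old CBA/CaJ mice, 1 library per mouse. Per the labels' protocols, total RNA was purified with the miRNeasy Mini Kit, degraded or contaminated samples were left out, and libraries were made with the TruSeq RNA kit. Whether the libraries keep strand is not given in the sources used here. Partek, TopHat2 and DESeq2 and the genome build mm10 are named in the submitters' processing notes, without versions or roles. The annotation is not given in the sources used here.

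The authors deposited 1 table of 17091 gene symbols with a value per library. Each deposited value is a signal, the read count of a gene divided by a size factor of its library. The low values of a library are whole multiples of 1 step (0.946 to 1.05), and division by that step gave numbers within 0.1 of a whole number in 99.9% of all values and in 100% of values under 10000. Reads recovered in this way summed to 37843857, 37055355 and 38179961 in young replicates 1, 2 and 3 and to 38010991, 39103398 and 37577315 in old replicates 1, 2 and 3. The depths differed by a factor of at most 1.055, and counting intervals cover counting error only. The authors' deposited table also holds a p-value, an adjusted p-value and a signed fold change per gene for old against young, and 332 genes have no adjusted p-value there. The mean of at least 1 per library that was set as a filter removed 0 genes. Every pair of libraries differed by more than sampling noise. Each sample is a separate mouse, so p-values measure the spread between animals.

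Before the data were examined, the test, the gene lists, the rule for named genes and most alternatives were fixed. The plan named edgeR for counts and limma for normalised values, and limma was used because the deposited values are normalised. Group differences were tested with limma 3.58.1 (trend and robust variance estimation, R 4.3.3) on log2(value + 1), with Benjamini-Hochberg adjustment over 17091 genes and a threshold of 0.05. Fold changes are on that log2 scale, which understates the change of genes with few reads, and ± marks the SE for log2 fold changes and the SD for group means. With 3 against 3 samples, an exact permutation test of a single value cannot go below p = 0.1, so none was run.

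Of 32 lists, 31 had at least 3 tested members. They cover marginal, intermediate and basal, spindle and root cells, fibrocytes, potassium and acid-base transport, interstitial matrix, basement membrane, macrophages, complement, antigen presentation, interferon response, B cells, T and NK cells, neutrophils, erythroid cells, bone, cartilage, vessels, hair and supporting cells, neurons, glia, muscle, oxidative phosphorylation, antioxidants, senescence, cytokines, lysosomes, cell cycle, protein folding, immediate early genes and ribosomal proteins. The list of sex-linked genes had Xist alone and was not tested. Some genes belong to more than 1 list, such as Itgax (macrophage and complement), Cd68 (macrophage and lysosome) and Ctss (antigen presentation and lysosome). Results of such lists are not independent. Lists were tested with camera (preset correlation 0.01), adjusted over the 31 lists, again with an estimated correlation, and with fry, which tests whether the members move in 1 direction on balance. Of the 31 lists, 22 were called by camera, 16 higher and 6 lower in old, 2 with an estimated correlation (cytokines and T and NK cells), and 11 by fry at an adjusted p under 0.05.

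The rule for named genes took the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 50 and no overlap between groups, without predicted or unnamed models, immunoglobulin and T cell receptor variable segments and sex-linked genes. It also took the 3 members of each list with the smallest p, and in every case Kcnq1, Kcne1, Kcnj10, Slc12a2, Gjb2, Gjb6, Slc26a4, Coch and Pou3f4. Some genes that the rule took are not reported here. Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 names, and 16941 of the symbols (99.1%) matched it or a synonym. Because strand is not stated, reads of the named genes Angptl7, Anxa1, Lgr5, Chad, Eng, Tagln, Plvap, Scn9a, Cnp, Prc1, Fkbp10, Ddit3 and Kcnq1 are uncertain, since each overlaps a gene on the opposite strand, and so are those of near-identical copies such as the haemoglobin genes.

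The alternatives were quantile normalisation, limma without trend, a mean of at least 10, pseudocounts of 0.1 and 10, the replicate number as a block, leaving out each library, stricter thresholds and the authors' deposited p-values. Added after seeing the data were edgeR 4.0.16 (TMM or DESeq2 size factors) and DESeq2 1.42.0 on the recovered reads, a correction for transcript length and GC content, and a blood and marrow score (the mean of the erythroid and neutrophil lists) or a nerve score (the mean of the neuron and glia lists) as a covariate. The edgeR fit on recovered reads called 905 genes and the DESeq2 fit 1819. The limma step was tested on simulated data, with 200 of 17046 genes changed at the real means, depths and dispersions for the comparison of old against young. The changed genes were drawn from those with a mean of at least 50, so the shares recovered do not cover genes with fewer reads. Limma recovered 19.4% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 95.5% of those changed 4-fold, and called 12 unchanged genes. The labels give no sequencing run. In the deposited column names young replicate 1 and old replicate 2 carry the same library number, so the libraries may come from more than 1 run. The names of the young libraries carry a hyphen and those of the old do not. Which libraries shared a run is not given in the sources used here, and a run effect was not tested. If young and old libraries were run apart, a run effect could not be told apart from age. Figures were drawn with matplotlib 3.10.9.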

Results

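RNA was sequenced from the cochlear lateral wall of CBA/CaJ mice, an inbred strain. The lateral wall holds the stria vascularis, the epithelium that secretes potassium into endolymph, and the spiral ligament beneath it. Samples came from 3 young mice aged 2 months and 3 old mice aged 2.5 years, and each sample pooled both cochleas of a mouse. The tissue label and the titles name the lateral wall, whereas the source label of all 6 samples names auditory nerve cells. The samples are called lateral wall here as in the study's design. The reads recovered from the deposited values ranged from 37055355 in young replicate 2 to 39103398 in old replicate 2. The question, as the study's title gives it, is which transcripts differ with age in this tissue. Xist, which is transcribed from an inactive X chromosome, stood at 24382 to 29162 normalised read counts in 5 libraries and at 45.2 in old replicate 3. The labels give no sex. The Y-linked genes of the sex-linked list, Ddx3y, Eif2s3y, Kdm5d and Uty, are not among the deposited symbols, so the sex of old replicate 3 stays open.

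Of 17091 genes tested, 898 differed between old and young lateral wall at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 463 of them higher and 435 lower in the old mice. A change of at least 2-fold was found in 360 of the higher and 190 of the lower genes. Among genes with a mean of at least 50, those with the largest rises included Itgax and Clec7a, which myeloid cells express. Those with the largest falls included the collagens Col1a2 and Col3a1 and the bone protein gene Bglap. The values of the groups did not overlap in 4457 genes (26.1%), where chance gives 10%. Young and old libraries separated on the first principal component, which held 47.3% of the variance. Across 13308 genes with a mean of at least 50, the median SD of the log2 values was 0.136 among the young and 0.177 among the old libraries. The limma count was 561 without young replicate 1, 288 without young replicate 2 and 230 without young replicate 3. Without old replicate 3, the library with little Xist, 256 genes were called higher. DESeq2 on the recovered reads called 1819 genes, and the authors' deposited table holds 1818 with an adjusted p under 0.05.

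**Figure D1:**
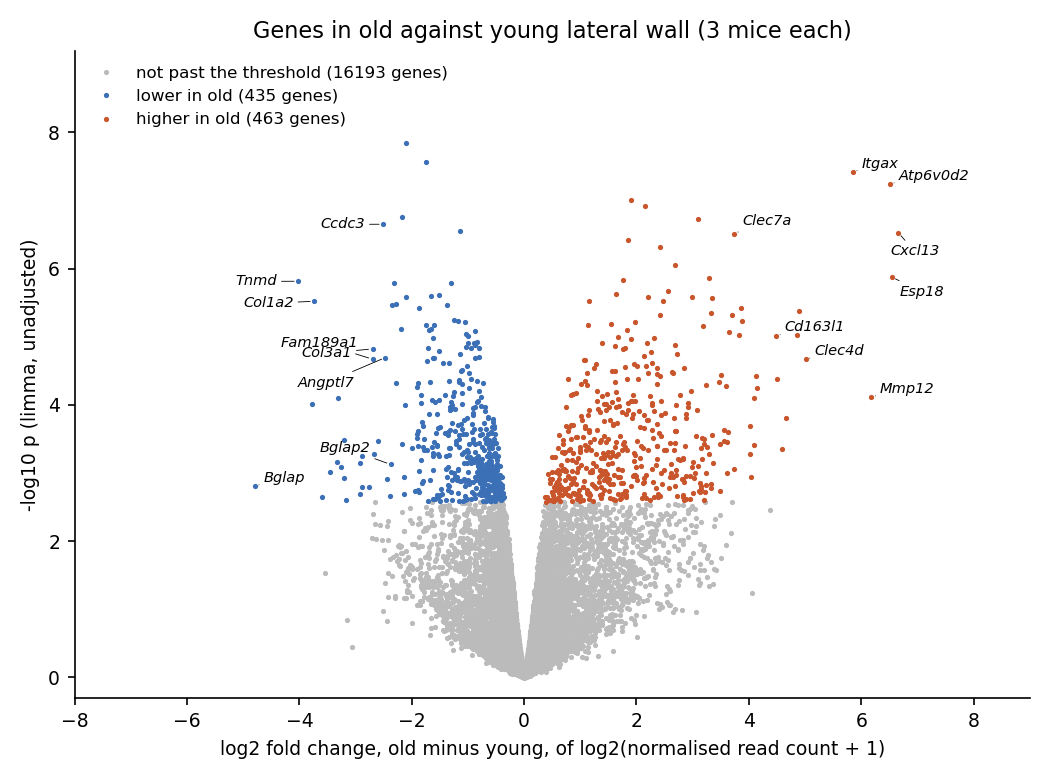
Each point is 1 of 17091 genes, with the log2 fold change of old against young lateral wall on the x axis and −log10 of the unadjusted limma p on the y axis (3 mice per group). Orange points are the 463 genes higher and blue points the 435 genes lower in old mice at an adjusted p under 0.05, and the 8 largest rises and 8 largest falls among genes with a mean of at least 50 are named.

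Among genes with a mean of at least 50, the 8 largest rises included genes of myeloid cells and of tissue remodelling. Itgax, which encodes the integrin CD11c of dendritic cells and some macrophages, averaged 5.52 ± 0.526 normalised read counts in young and 399 ± 162 in old mice (SD, n = 3 each). Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, rose from 4.15 ± 1.09 to 512 ± 281, and Mmp12, the macrophage elastase, from 18.1 ± 18.5 to 981 ± 340. The log2 fold changes, old minus young on the log2(value + 1) scale, were 5.85 ± 0.36 for Itgax, 6.51 ± 0.41 for Atp6v0d2 and 6.18 ± 0.77 for Mmp12 (SE). Their limma adjusted p were 0.000217, 0.000242 and 0.00791. Cxcl13, a chemokine that attracts B cells, had 3 reads in all young libraries together and 611 in the old, a ratio of 188.5 with a 95% counting interval of 64.2 to 917. Esp18, of the exocrine gland-secreted peptide family, had 2 reads in the young and 470 in the old libraries, a ratio of 217.5 (59.9 to 1801). Reads shared within that family make its value uncertain. The C-type lectin genes Clec4d and Clec7a and the scavenger receptor gene Cd163l1 rose by 5.01 ± 0.61, 3.74 ± 0.29 and 4.48 ± 0.51 on the log2 scale. In GRCm38 (mm10), Itgax lies on chromosome 7 from 128129547 to 128150657, Atp6v0d2 on chromosome 4 from 19876841 to 19922605, Mmp12 on chromosome 9 from 7344381 to 7369499 and Cxcl13 on chromosome 5 from 95956951 to 95961068. Clec7a lies on chromosome 6 from 129461591 to 129472779, and all values are counts over the whole gene. The call of Mmp12 was lost without young replicate 2 (limma adjusted p = 0.0631, range without 1 library 0.00494 to 0.0631).

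The 8 largest falls at that mean included genes of fibrous matrix, tendon and bone. Col1a2, a chain of type I collagen, averaged 9214 ± 719 normalised read counts in young and 736 ± 292 in old mice, a log2 fold change of −3.73 ± 0.30 (SE, limma adjusted p = 0.00161). The gene of the other chain, Col1a1, stood far lower in young mice and its mean fell less, as given under other observations. Col3a1, the chain of type III collagen, fell from 714 ± 194 to 112 ± 40.9, and Tnmd, which encodes the tendon protein tenomodulin, fell from 349 ± 69.4 to 22.3 ± 12.7. Ccdc3, Fam189a1 and Angptl7 were lower in old mice, with log2 fold changes of −2.51, −2.70 and −2.47. Bglap and Bglap2, neighbouring and near-identical genes of osteocalcin, had log2 fold changes of −4.79 ± 0.95 and −2.37 ± 0.46, and their reads cannot be assigned with certainty to either copy. Angptl7 lies within Mtor on the opposite strand and Fam189a1 overlaps Nsmce3, so reads of these pairs are uncertain as well. Col1a2 lies on chromosome 6 from 4504814 to 4541544, Col3a1 on chromosome 1 from 45311538 to 45349706, Tnmd on chromosome X from 133850980 to 133865577, Ccdc3 on chromosome 2 from 5137776 to 5230878 and Bglap on chromosome 3 from 88383501 to 88384464. The call of Bglap was lost in 5 of the 6 runs without 1 library (every library but old replicate 2), with adjusted p up to 0.141, and that of Bglap2 without young replicate 1 (0.079) and without young replicate 2 (0.107). At a fixed blood and marrow score Bglap had −2.34 and Bglap2 −1.58, and neither was called (limma adjusted p of 0.262 and 0.315). The scores of old and young mice do not overlap, so that fit cannot separate blood and marrow from age.

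**Figure D2:**
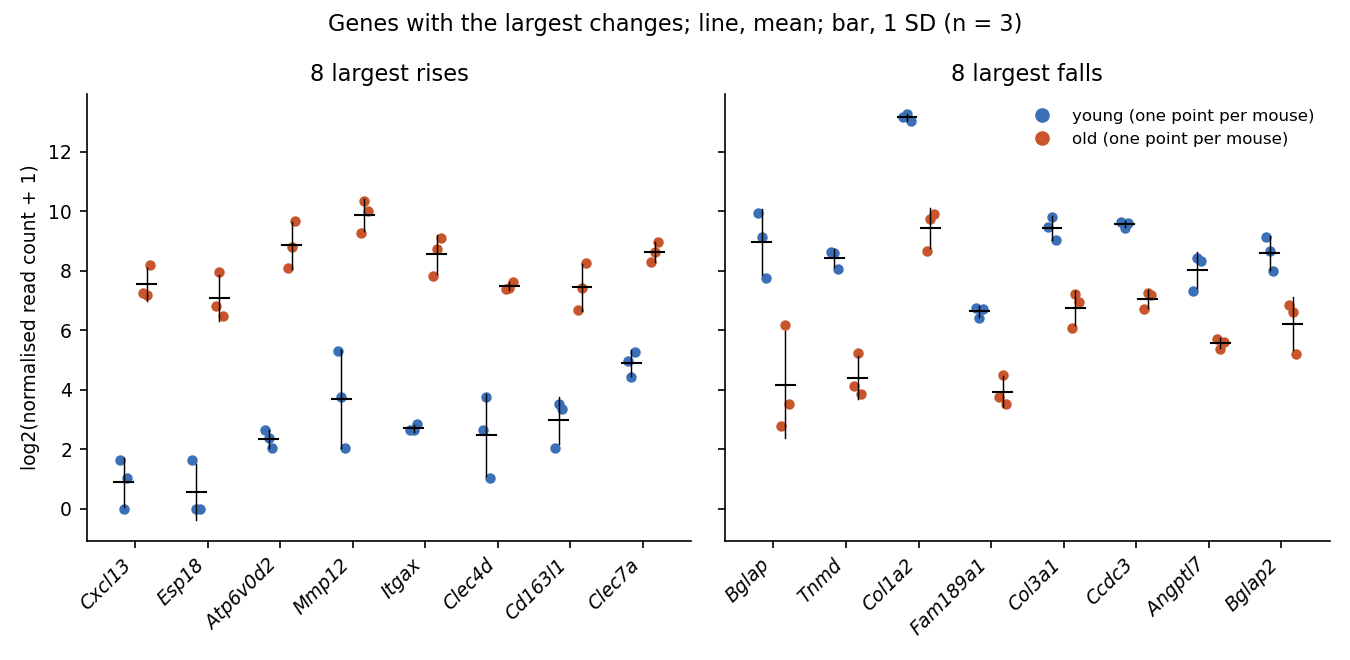
The y axis gives log2(normalised read count + 1) of the 8 genes with the largest rises (left) and the 8 with the largest falls (right) among those with a mean of at least 50, with a point per mouse, blue for young and orange for old, a line at the mean and a bar of 1 SD (n = 3). The rule that named these genes required that old and young values do not overlap, and Cxcl13 and Esp18 lie near 0 in the young mice.

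Transcripts of macrophages and of the molecules they use to take up and present material were higher in old lateral wall. Of 33 tested macrophage and monocyte markers, 20 rose and 0 fell (26 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 1.40. Lyz2, which encodes lysozyme, rose from 1876 ± 276 to 16286 ± 4688 normalised read counts (log2 fold change 3.09 ± 0.20, limma adjusted p = 0.000392), and Cd68, a lysosomal protein of macrophages, from 387 ± 36.5 to 1737 ± 281. Of 25 complement genes, 9 rose and 0 fell (14 and 0 adjusted over the list alone). Among them were C3ar1, the receptor for C3a (1.83 ± 0.21), and Itgb2, a complement receptor chain (2.42 ± 0.20). Of 26 antigen presentation genes, 9 rose and 0 fell (15 and 0 adjusted over the list alone), including the invariant chain gene Cd74 (1.55 ± 0.17) and the class II gene H2-Eb1 (2.28 ± 0.29). Of 48 cytokine and chemokine genes, 17 rose and 0 fell (24 and 0 adjusted over the list alone), including Il2rg (2.56 ± 0.25) and Cxcl1 (3.82 ± 0.44). Among 38 lysosome genes, 7 rose and 1 fell (10 and 2 adjusted over the list alone), including Ctss (1.90 ± 0.13) and Cd68 (2.15 ± 0.15). Their median log2 fold change was 0.01, and −0.02 to 0.05 without 1 library. The camera adjusted p over the 31 lists was 1.46e-18 for macrophage markers, 1.06e-07 for complement, 9.42e-12 for antigen presentation, 2.38e-12 for cytokines and 0.0418 for lysosome genes. With an estimated correlation, the adjusted p was 0.143 for macrophage markers, 0.0981 for complement, 0.0981 for antigen presentation, 0.0274 for cytokines and 0.43 for lysosome genes. Of these lists, cytokines alone kept the call. The lysosome list call was also lost without young replicate 2 (adjusted p = 0.0779), young replicate 3 (0.0722) or old replicate 2 (0.122), with the length and GC correction (0.0684) and with a nerve score as covariate (0.183).

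Lymphocyte transcripts were higher in all 3 old libraries, and transcripts of blood and marrow cells mainly in old replicates 1 and 3. Of 20 T and NK cell markers, 7 rose and 0 fell (11 and 0 adjusted over the list alone), including Ccl5 (log2 fold change 2.64 ± 0.35), Pdcd1 (4.10 ± 0.61) and Cd3g (4.02 ± 0.68). The list was called with the preset correlation (camera adjusted p = 8.06e-09) and with an estimated correlation (adjusted p = 0.0438). Of 15 B and plasma cell markers, 3 rose and 0 fell (5 and 0 adjusted over the list alone), namely Blk (3.87 ± 0.40), Cd22 (2.68 ± 0.46) and Jchain (3.61 ± 0.64). The list had camera adjusted p = 0.0102 and adjusted p = 0.328 with an estimated correlation. Of 22 neutrophil and marrow markers, 4 rose and 0 fell (19 and 0 adjusted over the list alone), including Csf3r (1.61 ± 0.30), Lcn2 (2.78 ± 0.51) and Padi4 (1.35 ± 0.28). The mean of this list lay 3.08, 0.73 and 3.87 log2 units above the young mean in old replicates 1, 2 and 3, and that of the erythroid list 2.80, 0.14 and 3.34 units above it. None of the 20 erythroid genes was called by limma (6 rose adjusted over the list alone, 12 had an unadjusted p under 0.05, and edgeR called 4 and DESeq2 10 higher). Rhag, Hbb-bt and Klf1 had log2 fold changes of 3.22 ± 0.78, 2.26 ± 0.63 and 1.38 ± 0.39 with adjusted p of 0.0507, 0.0764 and 0.0765. The camera adjusted p was 7.27e-12 for neutrophil and 4.04e-07 for erythroid genes, and the adjusted p with an estimated correlation was 0.319 and 0.425. The 45 cell cycle genes followed the same libraries, with list means of 0.81, 0.00 and 1.05 in old replicates 1, 2 and 3, camera adjusted p = 2.09e-05 and adjusted p = 0.425 with an estimated correlation. Of these, limma called 0, over all genes or adjusted over the list alone, edgeR called 0 and DESeq2 6, and 9 higher and 1 lower had an unadjusted p under 0.05. With a blood and marrow score as covariate the cell cycle list was not called (adjusted p = 0.991). E2f8, Rrm1 and Prc1 had log2 fold changes of 2.47 ± 0.66, 0.41 ± 0.11 and 1.09 ± 0.31. Of 46 interferon-stimulated genes, 2 rose, Oas2 (3.32 ± 0.70) and Trim30a (2.14 ± 0.46), and 0 fell (5 and 0 adjusted over the list alone), while Gbp5 had 1.17 ± 0.30 and an adjusted p of 0.0576. The interferon list mean was 2.06 in old replicate 1 and 0.27 and 0.29 in old replicates 2 and 3, with camera adjusted p = 3.83e-09 and adjusted p = 0.456 with an estimated correlation. Without old replicate 1 the interferon median was 0.22 against 0.74. The B cell list had a median of 0.25 without old replicate 3 and of 0.91 without old replicate 2, where its call was lost (adjusted p = 0.071). Leaving out young replicates 2 or 3 ended the calls of Cd22, Jchain, Csf3r, Lcn2, Padi4, Oas2 and Trim30a (adjusted p up to 0.0619, 0.0826, 0.0897, 0.105, 0.112, 0.152 and 0.165). Those of Jchain, Lcn2, Padi4, Oas2 and Trim30a were also lost without young replicate 1, those of Oas2 and Trim30a without old replicate 3, and that of Padi4 without old replicates 1 or 2. With quantile normalisation Oas2 and Padi4 were not called (0.0576 and 0.065), nor was Oas2 with a pseudocount of 10 (0.0586) or Cd3g with one of 0.1 (0.0634). The B cell list was not called with a nerve score as covariate (adjusted p = 0.125). Without old replicate 2, Gbp5, Rhag, Hbb-bt, E2f8 and Rrm1 passed (adjusted p of 0.0233, 0.00751, 0.0275, 0.00515 and 0.0339).

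**Figure D3:**
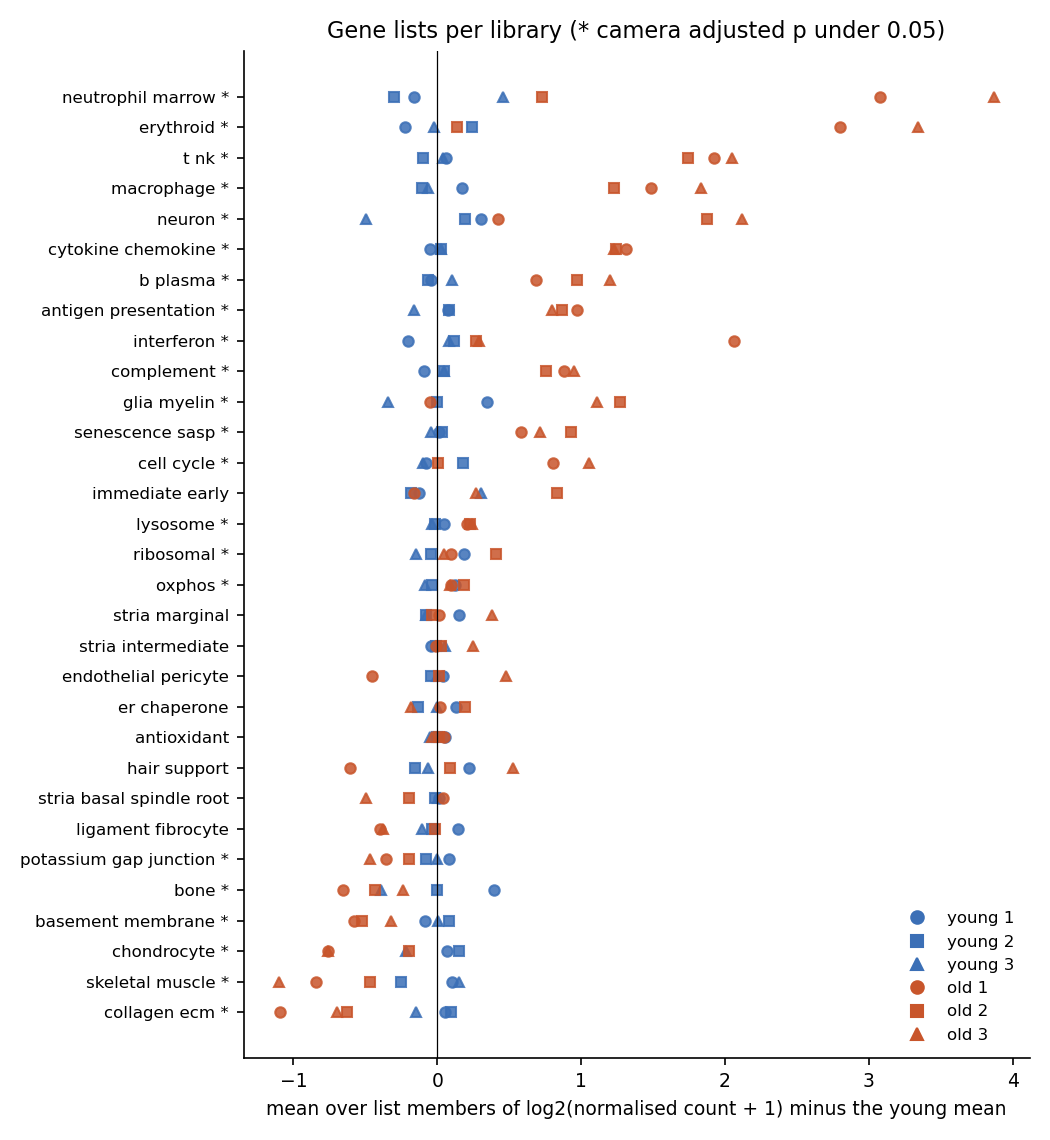
Each row is a gene list fixed before the data were examined, and each point is a library, placed on the x axis by the mean over the list's members of log2(normalised read count + 1) minus the young mean (blue young, orange old, symbols for replicates 1 to 3). Macrophage markers lie at 1.49, 1.23 and 1.84 in old replicates 1, 2 and 3, whereas erythroid genes lie at 2.80, 0.14 and 3.34 and neuron markers at 0.43, 1.88 and 2.12. A star marks lists with a camera adjusted p under 0.05.

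Genes of the interstitial matrix and of basement membranes were lower in old lateral wall. Of 42 interstitial matrix genes, 17 fell and 1 rose (21 and 1 adjusted over the list alone), with a median log2 fold change of −0.78. Besides Col1a2, the members with the smallest p were Col11a1, a chain of type XI collagen, with a log2 fold change of −1.37 ± 0.14, and Col6a1, a chain of type VI collagen, with −1.88 ± 0.19. The member that rose was Col14a1 (1.79 ± 0.33), named after its value was seen. Of 25 basement membrane genes, 9 fell and 0 rose (17 and 0 adjusted over the list alone), including the laminin gene Lama2 (−0.87 ± 0.10) and the type IV collagen genes Col4a3 (−1.90 ± 0.26) and Col4a6 (−1.23 ± 0.19). Camera gave adjusted p = 7.55e-14 for interstitial matrix and 1.31e-09 for basement membrane, and adjusted p = 0.101 and 0.0981 with an estimated correlation. Of 14 cartilage markers, 4 fell and 0 rose (5 and 0 adjusted over the list alone), including Col2a1 (−1.62 ± 0.18), Acan (−1.34 ± 0.19) and Chad (−0.96 ± 0.19). Several cartilage markers, Col2a1 and Acan among them, are also members of the interstitial matrix list. The list had camera adjusted p = 3.01e-05 and adjusted p = 0.23 with an estimated correlation. Of 21 bone markers, 8 fell and 2 rose (10 and 3 adjusted over the list alone). The osteocyte genes Phex and Dmp1 fell (−2.35 ± 0.24 and −1.26 ± 0.14), whereas the osteoclast gene Atp6v0d2 was among the largest rises. The bone list had camera adjusted p = 0.00835 and adjusted p = 0.43 with an estimated correlation. Of 23 skeletal muscle genes, 2 fell and 0 rose (7 and 1 adjusted over the list alone). Myh1, a myosin heavy chain gene, had 38 reads in the young and 0 in the old libraries and was at least 13.7-fold lower against a floor of 3 reads over the group. Mb fell by 2.61 ± 0.47, and Casq1 had a log2 fold change of −1.46 ± 0.40 with an adjusted p of 0.0746. The muscle list had camera adjusted p = 0.00709 and adjusted p = 0.319 with an estimated correlation. With a blood and marrow score as covariate the cartilage median was −0.14 against −0.62 and the muscle median −0.39 against −0.90, and neither list was called (adjusted p of 0.13 and 0.413). The bone list call was lost without young replicate 1 (adjusted p = 0.0736), and its median was −0.89 without old replicate 3 against −0.56. Casq1 passed without young replicate 1 (adjusted p = 0.0133). The calls of Col4a6 and Myh1 were lost without young replicate 3 (0.0654 and 0.0704), and that of Mb without young replicate 1 (0.0668) or young replicate 3 (0.0897). The call of Chad was lost in 4 of the 6 runs without 1 library (all but those without old replicates 1 and 2), with adjusted p up to 0.0983.

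Genes of potassium cycling and deafness that were fixed beforehand, from Kcnq1 to Pou3f4 here, were not called by limma, edgeR or DESeq2, while single markers of the stria and ligament were. Kcnq1 and Kcne1, the subunits of the potassium channel of marginal cells, had log2 fold changes of −0.20 (95% interval −0.53 to 0.13) and −0.07 (−0.38 to 0.24). Kcnj10, the potassium channel of intermediate cells, had −0.07 (−0.56 to 0.42), and the cotransporter gene Slc12a2 had −0.09 (−0.40 to 0.22). With quantile normalisation Kcne1, Kcnj10 and Slc12a2 had 0.07, 0.01 and 0.13, on the other side of 0. The gap junction genes Gjb2 and Gjb6 had −0.33 (−0.72 to 0.05) and −0.32 (−0.69 to 0.06). The anion exchanger gene Slc26a4 had −0.53 (−1.22 to 0.17), and the fibrocyte genes Coch and Pou3f4 had −0.75 (−1.34 to −0.15) and −0.52 (−1.05 to 0.02). The limma adjusted p of Coch was 0.148, and Coch had −0.27 with quantile normalisation. With a blood and marrow score as covariate Gjb2, Gjb6, Coch and Pou3f4 had 0.13, 0.08, 0.05 and 0.16, and with a nerve score Slc26a4 had 0.24. Without old replicate 2, Kcnj10 and Slc12a2 had 0.17 and 0.02, and without young replicate 1 Kcne1 had 0.03. Among 17 marginal cell markers, Kcnk2, a potassium channel gene, rose by 2.20 ± 0.29 and Atp1b2, a sodium pump subunit gene, fell by 0.61 ± 0.12 (1 and 1 adjusted over the list alone), and Lrp2 had −0.44 ± 0.16. The median of these markers was −0.07, or 0.07 with quantile normalisation, their mean was 0.12 and camera pointed up. Among 18 intermediate cell markers, 3 rose and 0 fell (5 and 1 adjusted over the list alone), namely the melanocyte genes Mlana (1.09 ± 0.14), Slc45a2 (0.54 ± 0.13) and Gpnmb (0.73 ± 0.17). At a fixed blood and marrow score Mlana, Slc45a2 and Gpnmb had 0.75, 0.27 and 0.30. None was then called (limma adjusted p of 0.0704, 0.401 and 0.443), but that fit cannot separate blood and marrow from age, since the scores of the groups do not overlap. Among 16 ligament fibrocyte markers, Otos, which encodes the secreted protein otospiralin, fell from 151382 ± 25884 to 46735 ± 12559 normalised read counts (log2 fold change −1.71 ± 0.20). It was the 1 call (also 1 adjusted over the list alone), while Tbx18 had −0.55 ± 0.17. None of 12 basal, spindle and root cell markers was called by limma (1 rose and 1 fell adjusted over the list alone, 2 higher and 2 lower had an unadjusted p under 0.05, and edgeR called 0 and DESeq2 1 higher and 1 lower). Anxa1, Lgr5 and Dpp10 had 0.73 ± 0.20, −0.95 ± 0.27 and −0.56 ± 0.21. Of 27 potassium cycling, acid-base transport and gap junction genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone), namely Atp1b2, the water channel gene Aqp1 (−2.14 ± 0.43) and the proton pump subunit gene Atp6v0a4 (−3.60 ± 0.85), whose reads overlap D630045J12Rik. Camera called this last list (adjusted p = 0.0327, and adjusted p = 0.23 with an estimated correlation) and not those of marginal (adjusted p = 0.983), intermediate (0.12), basal, spindle and root (0.164) or fibrocyte markers (0.0644).

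Several of these calls changed when 1 library was left out or an alternative was used. The transport list call was lost without young replicate 1 (adjusted p = 0.181), with quantile normalisation (0.272) with a correction for length and GC content (0.0663) and with a blood and marrow score as covariate (0.0778), and its median was −0.09 without old replicate 1 against −0.17. Camera called the fibrocyte list without old replicate 2 (adjusted p = 0.00275), young replicate 2 (0.0457) or young replicate 3 (0.0109). It also called the intermediate cell list without old replicate 2 (0.032), with quantile normalisation (0.0411) and with a mean of at least 10 (0.0496), and the basal, spindle and root list without old replicate 1 (0.0341). Coch, Pou3f4 and Tbx18 passed the limma threshold without old replicate 2 (adjusted p of 0.00448, 0.0154 and 0.00448), Slc26a4 and Lgr5 without old replicate 1 (0.0297 and 0.00972). Lrp2 and Anxa1 passed without old replicate 3 (0.017 and 0.0409). The calls of Atp1b2, Slc45a2, Gpnmb, Aqp1 and Atp6v0a4 were lost without young replicates 1, 2 or 3 or old replicate 1, with adjusted p up to 0.125, 0.189, 0.166, 0.162 and 0.15, and those of Slc45a2, Aqp1 and Atp6v0a4 also without old replicate 3. With quantile normalisation Atp1b2 had −0.34 (adjusted p = 0.195) and Aqp1 −2.07 (0.0548), and neither was called. The call of Atp6v0a4 was also lost with edgeR (adjusted p of 0.0747 and, with DESeq2 size factors, 0.0722), the length and GC correction (0.0545), a mean of at least 10 (0.0513) and a pseudocount of 0.1 (0.1). Its change was −1.74 with a pseudocount of 10. At a fixed blood and marrow score Atp6v0a4 had −0.98 and was not called (limma adjusted p = 0.537). At that score Aqp1 had −0.84 and kept its call (0.0372), and Atp1b2 had −0.77 and lost it (0.065). The marginal cell median was −0.16 without old replicate 3 and 0.02 without old replicate 2. With a blood and marrow score as covariate it was −0.25 and camera called the list lower (adjusted p = 0.0189), and with a nerve score camera called the fibrocyte list (0.00208).

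**Figure D4:**
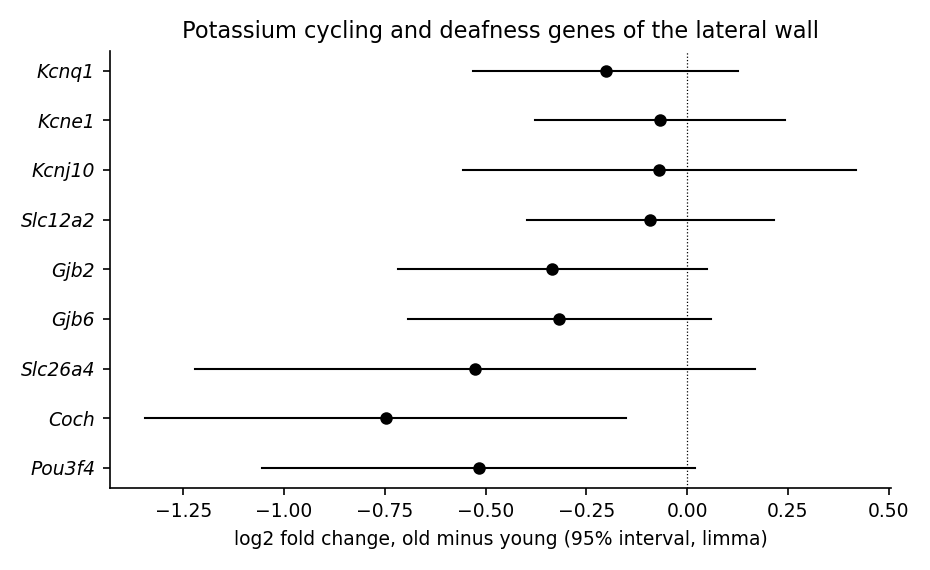
Points give the limma log2 fold change of potassium cycling and deafness genes, old minus young, and bars its 95% interval (3 mice per group). All points lie below 0, from −0.07 in Kcne1 to −0.75 in Coch, though Kcne1, Kcnj10 and Slc12a2 lie above 0 with quantile normalisation, Gjb2, Gjb6, Coch and Pou3f4 with a blood and marrow score and Slc26a4 with a nerve score as covariate, and all intervals but that of Coch include 0.

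Neuron transcripts were higher mainly in old replicates 2 and 3. Of 28 neuron markers, 7 rose and 2 fell (13 and 2 adjusted over the list alone). Stmn2, a microtubule regulator of neurons, rose by 3.16 ± 0.53 and Sncg by 1.63 ± 0.29, and Scn9a, a sodium channel gene, had 1 read in the young and 46 in the old libraries, a ratio of 42.6 (95% counting interval 7.27 to 1718). The neuron list mean lay 0.43, 1.88 and 2.12 log2 units above the young mean in old replicates 1, 2 and 3, and that of 24 glia and myelin markers lay at −0.05, 1.27 and 1.11. Of the glia markers, 2 rose and 1 fell (4 and 2 adjusted over the list alone), among them the myelin gene Cnp, which rose by 0.58 ± 0.13, and the fatty acid binding protein gene Fabp7, which fell (−1.80 ± 0.30). Camera gave adjusted p = 4.73e-07 for neuron and 0.00256 for glia markers, and adjusted p = 0.384 and 0.435 with an estimated correlation. Of 27 hair cell and supporting cell markers, Calb1 (3.15 ± 0.59) and Otog (0.78 ± 0.18) rose and 0 fell (2 and 0 adjusted over the list alone), and Pvalb had 2.08 ± 0.67 with an adjusted p of 0.132. This list's median was −0.17 and its mean 0.00, and camera gave adjusted p = 0.582. None of 29 endothelial cell and pericyte markers was called by limma (0 adjusted over the list alone, 1 higher and 5 lower at an unadjusted p under 0.05, 0 by edgeR, and 1 higher and 3 lower by DESeq2). Eng, Tagln and Plvap had −0.38 ± 0.10, −0.97 ± 0.27 and −0.69 ± 0.20. The endothelial list's median was 0.15 (−0.15 to 0.35 without 1 library), with 18 members above 0 and 11 below. Camera pointed up with adjusted p = 0.73. Camera called the endothelial list higher without old replicate 1 (median 0.35, adjusted p = 0.0035) and the hair cell list lower without old replicate 3 (median −0.17, adjusted p = 0.0211). With a nerve score as covariate camera called the endothelial list lower (median −0.39, adjusted p = 3.03e-05) and the hair cell list (median −0.68, adjusted p = 0.00118). The hair cell list's median was −0.37 without young replicate 2 and −0.01 without young replicate 1 or old replicate 1. The calls of Stmn2, Sncg, Scn9a, Cnp and Otog were lost without young replicate 2 (adjusted p of 0.0528, 0.069, 0.054, 0.124 and 0.135), and those of Sncg, Scn9a, Cnp, Otog, Calb1 and Fabp7 without young replicate 3 (0.0833, 0.0612, 0.165, 0.119, 0.0536 and 0.0713). Those of Otog, Calb1 and Fabp7 were also lost without young replicate 1 (0.073, 0.0542 and 0.0524). Without old replicate 3 the calls of Sncg, Scn9a, Cnp, Otog and Calb1 were lost (0.0537, 0.0506, 0.0714, 0.0784 and 0.0518), and those of Cnp and Otog without old replicate 2 (0.0596 and 0.0715). Eng and Plvap passed without old replicate 2 (0.0397 and 0.00915), Tagln without old replicate 3 (0.0401) and Pvalb without old replicate 1 (0.00214).

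Genes of the senescence list changed in both directions, and no gene of oxidative phosphorylation or ribosomal proteins was called by limma, edgeR or DESeq2. Of 36 cell cycle arrest and secretory genes, 4 rose and 3 fell (9 and 4 adjusted over the list alone). Plaur, the urokinase receptor gene, rose by 2.37 ± 0.33 and Cxcl1 rose as given above, whereas Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 9981 ± 583 to 4862 ± 644 normalised read counts (log2 fold change −1.04 ± 0.11, limma adjusted p = 0.00226). Camera gave adjusted p = 0.0036 for this list and adjusted p = 0.23 with an estimated correlation. With a nerve score as covariate its median was 0.20 against 0.48 and its call was lost (adjusted p = 0.183). Of 42 antioxidant genes, the metallothionein genes Mt1 and Mt2 fell (−0.93 ± 0.21 and −1.40 ± 0.31) and 0 rose (0 and 0 adjusted over the list alone), and Txn1 had 0.36 ± 0.10, with camera adjusted p = 0.582. Of 30 protein folding genes, Fkbp10, a collagen chaperone gene, fell by 0.83 ± 0.13 and 0 rose (1 and 0 adjusted over the list alone), while Hspa8 and Ddit3 had 0.50 ± 0.15 and −0.43 ± 0.14. The median of this list was 0.03, or 0.00 with a correction for length and GC content, while camera pointed down (adjusted p = 0.909). None of 75 oxidative phosphorylation genes, 42 ribosomal protein genes or 22 immediate early genes was called by limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 7 higher, 9 higher, and 4 higher and 2 lower genes, and DESeq2 called 3 higher and 1 lower immediate early genes and edgeR 0. Their medians were 0.13, 0.23 and 0.32, and camera gave adjusted p = 8.91e-05, 5.68e-05 and 0.113. With an estimated correlation, the adjusted p was 0.527 for oxidative phosphorylation and 0.527 for ribosomal protein genes. Ndufs7, Cycs and Ndufb10 had log2 fold changes of 0.31 ± 0.11, 0.25 ± 0.09 and 0.24 ± 0.09. Rps20, Rps9 and Rpl22 had 0.41 ± 0.13, 0.31 ± 0.10 and 0.31 ± 0.10, and Cyr61, Klf6 and Ier5 had −0.62 ± 0.17, 0.51 ± 0.14 and 0.47 ± 0.15. Camera called the immediate early list without young replicate 3 (adjusted p = 0.0129) or old replicate 1 (0.0017), and its median was 0.16 without young replicate 2 and 0.09 without old replicate 2. With a blood and marrow score as covariate its median was 0.66 and it was called (adjusted p = 0.000414). The oxidative phosphorylation median was 0.20 without young replicate 1 and 0.08 without young replicate 3, and that list's call was lost with a correction for length and GC content (adjusted p = 0.235). The ribosomal median was 0.09 without old replicate 2. With a nerve score as covariate the oxidative phosphorylation and ribosomal medians were 0.06 and 0.05, and neither list was called (adjusted p of 0.237 and 0.369). The protein folding median was −0.10 without old replicate 2 and 0.11 without old replicate 3, and with a blood and marrow score as covariate it was 0.24 and camera called the list higher (adjusted p = 0.00249). The calls of Mt1 and Mt2 were lost without young replicates 2 or 3 or old replicates 2 or 3 (adjusted p up to 0.161 and 0.161), that of Mt1 also without old replicate 1 (0.0637), and that of Fkbp10 without young replicate 3 (0.05). Mt1 and Mt2 were not called with quantile normalisation (0.0696 and 0.0625). Hspa8 passed without young replicate 1 (0.0331) and Cyr61 and Klf6 without old replicate 2 (0.00792 and 0.0386).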

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

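The counts on recovered reads, the correction for length and GC content and both covariate fits were added after the data were seen. All 70 called genes that the naming rule took kept their direction under every alternative in which they were tested, and 40 kept their call in all 6 runs without 1 library. Of these 70, 27 lost it without the trend, 18 with the replicate block, 6 with quantile normalisation, 43 with the blood and marrow score and 36 with the nerve score. The calls numbered 788 to 909 with quantile normalisation, a mean of at least 10, both pseudocounts, both edgeR fits and the length and GC correction, against 898. Without the trend, limma called 307 genes, 194 higher and 113 lower. DESeq2 on recovered reads called 1819 genes, 976 higher and 843 lower, and the authors' deposited p-values 1818, 975 higher and 843 lower, including 892 of the 898. In the simulated comparison DESeq2 called 39 unchanged genes and limma 12; the cause of the higher count in the real data was not tested. At an adjusted p under 0.01, 210 genes passed, 119 higher and 91 lower, and with at least a 2-fold change 550, of which 190 were lower, since fewer genes meet a stricter threshold. Runs without 1 library, which have fewer samples, called 230 to 1136 genes, 139 to 554 higher and 91 to 582 lower. With the replicate number as a block, 406 genes were called, 230 higher and 176 lower, but the numbers do not pair the samples (correlations of deviations −0.12, −0.05 and −0.08 for replicates 1, 2 and 3). The block changed 1 list call, that of fibrocyte markers (adjusted p = 0.038).

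With a blood and marrow score as covariate, 150 genes were called, 43 higher and 107 lower, and with a nerve score 171, 98 higher and 73 lower. These fits leave fewer degrees of freedom. The blood and marrow scores of the groups do not overlap, so that fit cannot separate them from age. A call lost there does not show that blood or marrow explains the change. Mmp12 (6.18 to 6.91) and Atp1b2 (−0.61 to −0.77) changed more at that score and still lost their calls (limma adjusted p of 0.123 and 0.065). Lists called numbered 18 to 25 in all other alternatives and 2 with an estimated correlation, against 22. Camera turned the direction of 6 lists that were called with or without a score. With the blood and marrow score these were marginal cell markers (median −0.25, called with adjusted p = 0.0189), protein folding genes (0.24, called with 0.00249), cell cycle genes (0.02, not called with 0.991) and erythroid genes (−0.24, not called with 0.557). With the nerve score they were endothelial markers (−0.39, called with adjusted p = 3.03e-05) and glia markers (−0.24, not called with 0.341). The blood and marrow score also ended the calls of transport genes (0.0778), cartilage (0.13) and muscle (0.413), and immediate early genes were called (0.000414). The nerve score also ended those of B cells (0.125), oxidative phosphorylation (0.237), senescence (0.183), lysosome (0.183) and ribosomal protein genes (0.369), and fibrocyte (0.00208) and hair cell markers (0.00118) were called. The erythroid and neutrophil lists make up the first score and the neuron and glia lists the second, so that their calls end holds by construction; for the other lists the cause was not tested. The no-filter alternative gave no separate value, because the filter removed 0 genes. Quantile normalisation and the length and GC correction ended the call of the transport list (adjusted p of 0.272 and 0.0663), and the correction those of oxidative phosphorylation (0.235) and lysosome genes (0.0684). The median log2 fold change of all genes stayed between −0.007 and 0.013 under every scaling. In the simulated comparison limma recovered 19.4% of genes changed 1.5-fold, all with a mean of at least 50. Changes of that size in such genes thus mostly stay below detection with 3 mice per group.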

Other observations

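Genes outside the rule, named after their values were seen, add to both sides of the comparison. Lgals3, which encodes galectin-3, rose by 2.69 ± 0.23 on the log2 scale, and the scavenger receptor genes Msr1 and Cd36 rose by 2.18 ± 0.26 and 2.17 ± 0.28 (limma adjusted p of 0.00101, 0.00301 and 0.00436). Trem2, a lipid receptor gene of macrophages, rose by 1.77 ± 0.21, and Fabp5, a fatty acid binding protein gene, by 3.24 ± 0.45. Among the genes that fell were Itga8 and Npnt, which encode an integrin chain and its matrix ligand nephronectin, with log2 fold changes of −2.11 ± 0.11 and −1.74 ± 0.10 (both limma adjusted p = 0.000217). Pdgfra, a growth factor receptor gene of fibroblasts, had −1.14 ± 0.09, and Lox, which encodes a collagen cross-linking enzyme, had −1.30 ± 0.20. Col1a1 averaged 795 ± 507 normalised read counts in young and 292 ± 214 in old mice, against 9214 ± 719 and 736 ± 292 for Col1a2 (SD, n = 3 each).

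The tests below, the correction for transcript length and GC content included, were chosen after the data were seen. The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split with as many calls: 898 genes against at most 0 in the other splits, 463 higher against 0, 435 lower against 0, and 22 lists against at most 17. Each other split puts young and old mice in both groups. An age or dissection difference then widens the spread within groups, so few calls there cannot decide about chance. In the other splits camera with its preset correlation called 11 to 17 lists, and up to 1281 genes had an unadjusted limma p under 0.05 against 3647 in the real split.

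Macrophage markers were higher in all 3 old libraries, and blood or marrow in the old dissections may have brought them. The blood and marrow score of old replicates 1, 2 and 3 lay 2.94, 0.45 and 3.62 log2 units above the young mean, and the haemoglobin gene Hbb-bs stood at 5238, 1524 and 9332 normalised read counts against 730 to 1073 in the young. Of the 42 genes in the score, 13 averaged at least 50 in young lateral wall. At a fixed score the median log2 difference of the macrophage list was 0.87 (quartiles 0.45 to 1.62) against 1.40 without it. The list stayed higher in old (limma's fry, adjusted p = 0.021 over 3 such tests). The young scores were −0.19 to 0.23. The groups do not overlap, so this fit cannot separate blood and marrow from age. In old replicate 2, whose score was nearest the young, the macrophage list mean lay 1.23 log2 units above the young mean. That is 1 library. How much of the rise came from blood and marrow stays open, as does age, the difference the design names.

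Interstitial matrix genes were lower in old, and less bone in the old dissections is a candidate explanation. The bone score, in log2 units relative to the young mean, was −2.25, −1.93 and −2.03 in old replicates 1, 2 and 3 and −0.56 to 0.54 in the young, so the score follows the groups. It rests on 9 bone genes, of which 8 averaged at least 50 in young lateral wall, and Ibsp stood at 282 to 1312 normalised read counts in the young and 78.5 to 299 in the old. At a fixed bone score the median log2 difference of the matrix list was −0.47 (quartiles −1.01 to 0.08) against −0.78 (limma's fry, adjusted p = 0.294), and bone and age cannot be told apart for these genes because the scores of the groups do not overlap. After correction for transcript length and GC content the median was −0.67 (quartiles −1.22 to −0.16; limma's fry, adjusted p = 0.0188), which argues against such a trend as the whole cause.

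Neuron markers were higher mainly in old replicates 2 and 3, and nerve tissue carried into old replicates 2 and 3 may account for it. Glia that wrap nerve fibres would then come along. Of 24 glia and myelin markers, 10 lay above every young library in old replicates 2 and 3 and not above the highest young library in old replicate 1, and 0 did so with either other old library as the exception. The glia list means of −0.05, 1.27 and 1.11 in old replicates 1, 2 and 3 had already shown this pattern. The count restates it and does not test the source. The abundant members S100b, Sox10, Pmp22 and Mal, chosen after their values were seen, did not follow it. S100b was no higher in old replicates 2 and 3 than in the young (322000 and 168300 against 309800 to 378800). Nor were Sox10 (5249 and 7753 against 5534 to 9013) and Pmp22 (6855 and 5726 against 5722 to 7608). Mal stood above every young library in old replicate 1 as well (9050, 8078 and 10830 in old replicates 1, 2 and 3 against 6953 to 7902). The tissue itself expresses 16 of the 24 at a mean of at least 50. In S100b, Sox10, Pmp22 and Mal, which are abundant in the young too, a small addition of nerve may not show. Their values therefore do not decide about nerve tissue, and a change with age stays open.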
